A study of Homo sapiens with 4 samples.

How the data were processed

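Primary human umbilical vein endothelial cells were compared in 2 groups of 2 arrays, a GFP lentivirus control and a GFP lentivirus overexpressing miR-335, and the labels give the group and replicate number of each array. Per the labels, the cells grew in EGM-2 medium, RNA was extracted with a miRNeasy kit and labelled with 1 dye by Illumina's expression profiling protocol.

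The authors deposited the average bead signal of 47322 probes per array, a linear intensity that had not been normalized between arrays, per the file headers. Beside each signal the authors deposited a detection p-value, by its name in the file headers a comparison with negative control probes. The software, its version and whether a background had been subtracted are not given in the sources used here. The median signals were 113.9 and 120.8 on the control arrays and 120.6 and 121.1 on the miR-335 arrays, and the lowest signals lay between 76.4 and 81.8. The authors also deposited normalized values of the same arrays. Their scale is linear, the values are not centred, and the columns share their quantiles, with medians of 118.2 on each array. Each column had the rank order of the raw signal of its own array (Spearman correlation 1.00), against at most 0.864 with another array. These values served as an alternative.

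Background correction and normalization used limma 3.58.1 in R 4.3.3. The function neqc estimated the background from the detection p-values, added an offset of 16, quantile normalized the arrays and took log2. Of the probes, 30113 had 1 gene symbol in the annotation table, 8 had several and 17201 had none; symbols were updated through gene identifiers with a RefSeq gene table of the GRCh38.p14 assembly for 30074 probes. Probes without a single symbol kept their probe number. The table was used only for names and for the class of an RNA, and no coordinates are given because the build of the array's design is not given in the sources used here. To print nothing that belongs to a donor, 144 probes of XIST, TSIX and Y-linked genes were left out.

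Probes with a detection p below 0.01 on both arrays of at least 1 group were kept, 14976 in all. For each gene the probe with the highest mean over all arrays stood for the gene, and each unnamed probe counted as a gene, which gave 9576 named genes and 2702 unnamed probes. Where a gene had more than 1 probe, the others were used only in the alternative that averages them. Differences were tested with lmFit and eBayes, with group as the only term, and p-values were adjusted by Benjamini and Hochberg over the 12278 genes; an adjusted p below 0.05 counts as a change. Arrays give no counts, so precision is set by the number of arrays and by signal over background, and the median SE of a log2 difference was 0.18. On simulated data with the spread of these arrays, the test called 2 of 50 genes changed by 0.5 log2 units, 34 of 50 changed by 1, 49 of 50 changed by 2, 50 of 50 changed by 3 and 5 of 12078 unchanged genes. Of simulated gene lists, the list test called 5 of 5 shifted by 0.3 and 0 of 15 unshifted ones. The simulated genes were drawn independently of one another. Members of real lists can move together (estimated correlation up to 0.66), so this does not show how often real lists are called falsely.

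The test, the filter, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule names, per direction, up to 12 named genes with the largest change among those that pass and whose groups do not overlap. Where none passes in a direction it names the 6 with the smallest p, said not to pass. It adds MIR335 and its host gene MEST, and up to 4 members of each gene list, first those that pass and then those with the smallest p. A few further members of a list were named from general knowledge or after their values were seen: SOX4, TNC, IFIH1, HERC5, ISG15, VWF, CDH5, PECAM1 and FBLN1.

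The 22 lists came from general knowledge: reported miR-335 targets; pan-endothelial identity; angiogenesis, tip cell and Notch; haemostasis and fibrinolysis; endothelial inflammatory activation; smooth muscle, pericyte and fibroblast markers; leukocyte and erythroid markers; epithelial markers; and TGF-beta and SMAD response. Others were extracellular matrix and basement membrane, interferon response, p53 targets and cell cycle arrest, G1/S and DNA replication, G2/M and mitosis, and unfolded protein response. The last were heat shock, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis and SREBP2 targets, large ribosomal proteins and small RNA machinery. Another list was tested with these and is not reported here. Lists with at least 5 tested genes, 20 of them, were tested with camera at a preset correlation of 0.01 between genes, two-sided, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, stand beside it. Fry's mixed test, which counts moves in either direction and gives a list no direction, is named as such. List medians were also set against 10000 random lists matched on mean level. Some listed genes were not analysed here.

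The alternatives were no background correction, an offset of 50, median scaling, the authors' normalized values, no filter, detection on all 4 arrays, a detection p below 0.05, the mean of a gene's probes, an intensity trend or a robust prior in eBayes, a fit without moderated variances, a minimum log2 change of 1, the replicate number as a block, and each array left out in turn. A planned test of genes whose 3' UTR matches the miR-335 seed was not run, since no 3' UTR sequence was used here.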

Results

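Human umbilical vein endothelial cells (HUVEC), primary cells that line the vein of the umbilical cord, had been transduced with a lentivirus carrying GFP or with a GFP lentivirus that overexpresses the microRNA miR-335. Total RNA was measured on Illumina bead arrays, with 2 arrays per group and 4 in all, a number that limits the precision of every value below. At a detection p below 0.01, 15629 and 15364 of the 47322 probes were detected on the control arrays, and 15580 and 15095 on the miR-335 arrays, which is 31.9% to 33.0%. Levels are normalised log2 intensities with the SD over the 2 arrays of a group, and differences are miR-335 minus GFP control on the log2 scale with the SE of the limma fit. Across the genes tested, the Pearson correlation was 0.992 between the control arrays, 0.988 between the miR-335 arrays and 0.981 to 0.989 between groups, over genes that are not independent replicates. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All 4 arrays shared 1 chip, with the controls at positions B and D and the miR-335 arrays at F and H. An effect of position on the chip therefore cannot be told apart from the group.

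The comparison asks which transcripts differ between endothelial cells that overexpress miR-335 and cells that carry the GFP vector. Of 12278 genes tested, 4 were higher and 1 was lower with miR-335. ACTA2, the smooth muscle alpha-actin gene (probe ILMN_1671703), rose from 7.85 ± 0.22 to 9.32 ± 0.03 (SD, n = 2), a difference of 1.47 ± 0.18 (SE) or 2.77-fold, with an adjusted p of 0.044. CCL23, which encodes a chemokine, was below detection on both control arrays and reached 6.61 ± 0.04 with miR-335, at least 2.15-fold higher (adjusted p = 0.023). The other CCL23 probe was not above background on any array. SCARNA14, a small Cajal body RNA, was also below detection in the controls and reached 6.78 ± 0.29, at least 2.41-fold higher (adjusted p = 0.034). An "at least" fold sets the brighter group against the higher of the dim probe's own signal and the lowest detected signal of each array. The remaining genes that passed were probes without a name in the annotation used here. ILMN_1745617, also below detection on both control arrays, was at least 2.08-fold higher (adjusted p = 0.0091), and ILMN_1675844 fell from 8.95 ± 0.09 to 7.19 ± 0.03, 3.38-fold lower (adjusted p = 0.014). CCL23, SCARNA14 and ILMN_1745617 thus passed the filter only through the miR-335 arrays, with control values near background.

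No named gene passed in the lower direction. The 6 named genes with the smallest p below 0 did not pass, and their groups did not overlap. GUCY1A1, a subunit of soluble guanylate cyclase, differed by −1.32 ± 0.17 (adjusted p = 0.052), and the zinc transporter gene SLC30A3 by −1.23 ± 0.16 (adjusted p = 0.061). The histone acetyltransferase gene KAT2B differed by −1.13 ± 0.16, the glypican gene GPC5 by −1.09 ± 0.17 and DCAF12L1 by −1.37 ± 0.22, each with an adjusted p of 0.090. The GUCY1A1 and DCAF12L1 probes were each detected on only 1 miR-335 array, and a second DCAF12L1 probe above background differed by −0.19. AFAP1L2, below detection on both miR-335 arrays, was at least 1.77-fold lower, also with an adjusted p of 0.090. At an unadjusted p below 0.05 there were 1641 genes, 837 higher and 804 lower, where 613.9 would be expected with no change. The groups did not overlap for 5538 genes, 45.1% of those tested, where chance gives 33.3%.

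**Figure D1:**
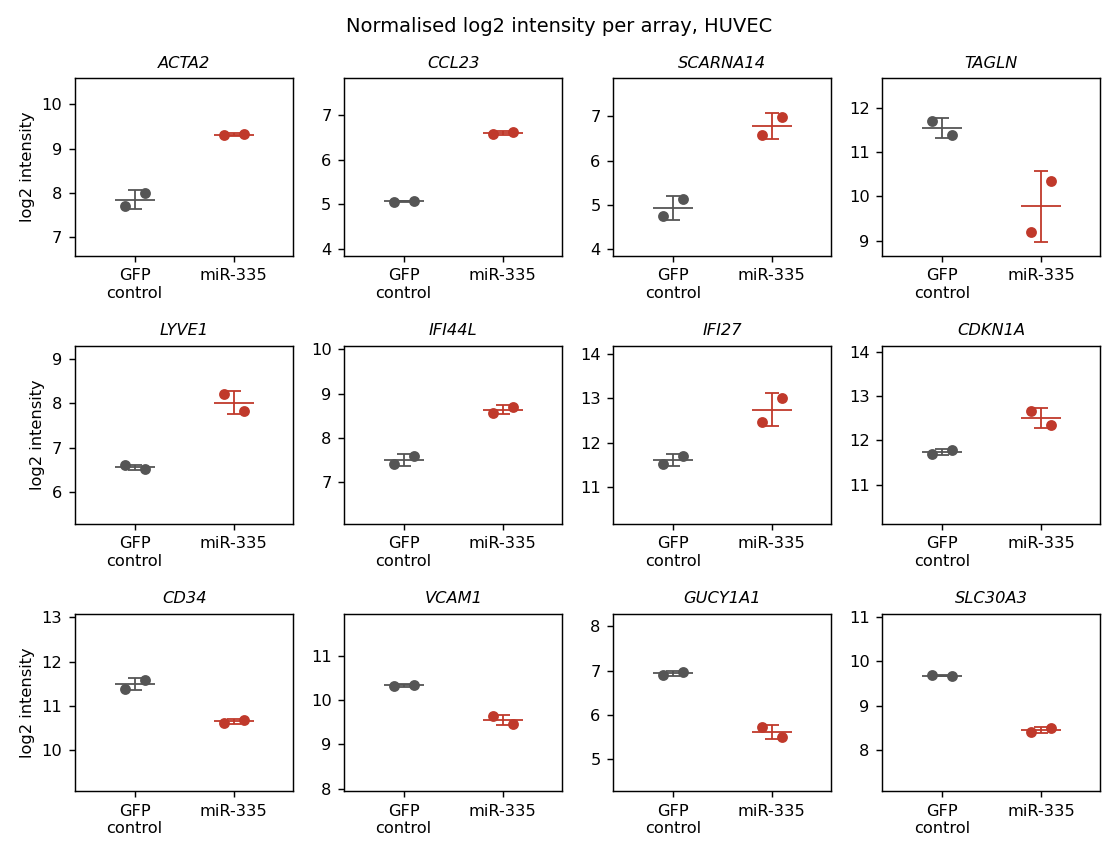
Normalised log2 intensity (vertical axis) of 12 genes on each array of GFP control cells (grey) and miR-335 cells (red). Points are arrays, horizontal bars are group means and whiskers are the SD over 2 arrays; each panel spans the same range of log2 units around its own centre. ACTA2, CCL23 and SCARNA14 passed the adjusted test, and the other 9 genes did not, among them TAGLN, whose miR-335 arrays spread most (SD 0.80).

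The count of changed genes moved widely with the processing: 119 genes passed without background correction, 116 in the authors' normalized values, 126 with an intensity trend in the variance prior, and 0 without the filter on dim probes. Leaving out either miR-335 array left 0 genes, and leaving out control replicate 1 or 2 gave 40 or 88.

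Whether the vector raised miR-335 could not be read from these arrays. The MIR335 probe had detection p-values of 0.34 and 0.083 on the control arrays and 0.16 and 0.073 on the miR-335 arrays, and none of the 3 probes of its host gene MEST was above background on any array, so neither checks the overexpression. Among 24 genes reported elsewhere as miR-335 targets, 15 were tested. Of these, 10 were lower and 5 higher with miR-335, with a median of −0.21 and a mean of −0.11, and the list was not called (camera adjusted p = 0.32). Its median lay at percentile 0.71 of random lists matched on level, whose 95% range was −0.17 to 0.15. Its mean shift against the other genes, −0.11, ran from −0.19 to −0.03 with an array left out. None passed over all genes or when adjusted over the list alone, and none reached an unadjusted p below 0.05. The smallest p belonged to DKK1, a Wnt antagonist (0.38 ± 0.17), followed by CALU (−0.36 ± 0.18), the transcription factor gene SP1 (−0.31 ± 0.16) and ARPC5L (−0.26 ± 0.20). SOX4 and TNC, among the best known reported targets, differed by −0.13 ± 0.17 and 0.12 ± 0.18, and the median 95% interval of the 15 genes extended 0.42 to either side. The small RNA machinery list, the enzymes and Argonaute proteins that make and use microRNAs, had a median of −0.01, a mean of 0.01 and no call (11 tested, camera adjusted p = 0.93). Its members with the smallest p were DICER1 (−0.33 ± 0.20), TARBP2 (0.26 ± 0.19), DGCR8 (0.22 ± 0.16) and AGO1 (0.20 ± 0.22), and none passed over all genes or adjusted over the list alone.

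Of the 20 gene lists with enough tested members, 3 were higher and 1 was lower with camera's preset correlation, and none of these calls held with an estimated correlation or with fry. With an estimated correlation, 0 of the 20 lists had even an unadjusted p below 0.05. The p53 list went from a camera p of 0.00010 to 0.052, although its estimated correlation of −0.029 lay below the preset 0.01. When camera estimates the correlation, it uses only the degrees of freedom left by these few arrays, which makes small p-values hard to reach. A call lost this way therefore does not by itself show that members move together or that the list did not shift. The interferon response list was higher, with 17 of 25 tested members above 0, a median of 0.23 and a mean of 0.29 (camera adjusted p = 0.0012; adjusted p = 0.72 with an estimated correlation). No member passed over all genes; adjusted over the list alone, 6 passed, all of them higher. These included IFI44L (1.14 ± 0.17), IFI27 (1.13 ± 0.21), IFIT1 (0.93 ± 0.21) and OAS2 (0.86 ± 0.17), all induced by type I interferon. A second IFI44L probe above background differed by 0.34. Members that did not follow included IFIH1, a sensor of viral RNA (−0.38 ± 0.19), and HERC5 (−0.31 ± 0.17), while ISG15 differed by 0.23 ± 0.23.

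The p53 target and cell cycle arrest list was higher, with 15 of 18 tested members above 0 and a median of 0.28 (camera adjusted p = 0.0012; adjusted p = 0.72 with an estimated correlation). Adjusted over the list alone, 1 member passed, CDKN1A, the p21 inhibitor of cyclin-dependent kinases, which was at 11.74 ± 0.06 in the controls and 12.50 ± 0.23 with miR-335. Over all genes it did not pass (difference 0.76 ± 0.18, adjusted p = 0.15). TIGAR (0.51 ± 0.17), the apoptosis effector gene BAX (0.50 ± 0.17) and CDKN2B (0.58 ± 0.23) reached an unadjusted p below 0.05 without passing either adjustment. A second probe above background gave 0.30 for BAX and 0.14 for CDKN2B. The G1/S and DNA replication list was also higher, with 21 of 26 tested members above 0 and a median of 0.20 (camera adjusted p = 0.016; adjusted p = 0.79 with an estimated correlation). None of its members passed over all genes or adjusted over the list alone. CCNE1, which encodes cyclin E1, differed by 0.61 ± 0.25, the replication licensing gene CDT1 by 0.51 ± 0.23, MCM10 by 0.45 ± 0.20 and GINS2 by 0.41 ± 0.19. The G2/M and mitosis list was not called (33 tested, median 0.06, camera adjusted p = 0.25). No member of it passed adjusted over the list alone, where NUF2 differed by 0.43 ± 0.19, PTTG1 by 0.43 ± 0.21, CCNB1 by 0.33 ± 0.16 and TOP2A by −0.40 ± 0.19.

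The pan-endothelial identity list was lower, with 23 of 28 tested members below 0 and a median of −0.19 (camera adjusted p = 0.016; adjusted p = 0.72 with an estimated correlation). Adjusted over the list alone, 1 member passed, the sialomucin gene CD34, at 11.49 ± 0.14 in the controls and 10.65 ± 0.05 with miR-335; over all genes it did not pass (−0.84 ± 0.17, adjusted p = 0.12). TIE1 (−0.35 ± 0.16) and EPAS1 (−0.39 ± 0.19) were below 0, EGFL7 was above it (0.50 ± 0.20), and the abundant markers VWF, CDH5 and PECAM1 differed by −0.03 ± 0.17, −0.22 ± 0.17 and −0.12 ± 0.18. A second EGFL7 probe above background differed by 0.17.

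Leaving out control replicate 1 took the mean shift of the G1/S list to 0.02 (adjusted p = 0.95) and of the endothelial list to −0.15 (adjusted p = 0.15); without miR-335 replicate 1 they were 0.06 (adjusted p = 0.66) and −0.19 (adjusted p = 0.068), and that of the p53 list was 0.24 (adjusted p = 0.066). Median scaling in place of quantile normalization ended the endothelial call (shift −0.13, adjusted p = 0.098).

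Several endothelial lists held members that moved apart, and none of these lists was called. In the list of angiogenesis, tip cell and Notch genes the median was −0.07, the mean was 0.03 and camera's direction was up (26 tested, camera adjusted p = 0.93). No member passed over all genes; adjusted over the list alone, 3 passed higher and 1 lower. LYVE1, a hyaluronan receptor of lymphatic endothelium, was at 6.55 ± 0.06 in the controls and 8.01 ± 0.27 with miR-335 (1.46 ± 0.19, adjusted p = 0.052). The chemokine receptor gene CXCR4 differed by 1.02 ± 0.18 and the protease gene ADAMTS1 by 0.84 ± 0.17, and the Notch ligand gene DLL4, below detection on both miR-335 arrays, was at least 1.32-fold lower. A second probe above background gave 0.66 for LYVE1 and 0.70 for CXCR4. The endothelial inflammatory activation list had a median of −0.14 (20 tested, camera adjusted p = 0.20). Adjusted over the list alone, 1 member passed higher and 3 lower, and none passed over all genes. The neutrophil chemokine gene CXCL6 differed by 1.11 ± 0.19, whereas the adhesion molecule gene VCAM1 differed by −0.78 ± 0.17 and the tethered chemokine gene CX3CL1 by −0.57 ± 0.17. SELE, which encodes E-selectin, was below detection on both miR-335 arrays and at least 1.36-fold lower. In the haemostasis and fibrinolysis list (14 tested, median 0.11, camera adjusted p = 0.47), none passed over all genes and 2 passed higher adjusted over the list alone, the urokinase gene PLAU (0.67 ± 0.17) and the cyclooxygenase gene PTGS1 (0.60 ± 0.17). PTGIS, which encodes prostacyclin synthase, differed by −0.51 ± 0.18 and PROS1 by −0.40 ± 0.16, and neither passed. For PTGS1 a second probe above background differed by 0.24.

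The smooth muscle, pericyte and fibroblast list was not called either (median 0.27, mean 0.11, camera adjusted p = 0.18), and only 7 of its 20 members were tested. ACTA2 passed over all genes; adjusted over the list alone, 3 members passed higher and 2 lower. The collagen gene COL3A1 differed by 0.91 ± 0.17 and RGS5, a pericyte marker, by 0.51 ± 0.16. TAGLN, the smooth muscle protein transgelin, went the other way, from 11.55 ± 0.23 to 9.78 ± 0.80 (−1.77 ± 0.32, adjusted p = 0.10 over all genes), and FBLN1 differed by −0.74 ± 0.24. The other 13 markers, among them CNN1, MYH11, PDGFRB and COL1A1, were not above background. Of 20 leukocyte and erythroid markers only 3 were tested, too few for a list test: CD68 differed by 0.44 ± 0.17, LAPTM5 by 0.35 ± 0.18 and CD14 by 0.31 ± 0.18. Of 12 epithelial markers 4 were tested, KRT19 (0.41 ± 0.23), KRT8 (0.27 ± 0.17), KRT7 (0.18 ± 0.17) and KRT18 (−0.13 ± 0.17), and no member of either list passed.

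In the TGF-beta and SMAD response list (10 tested, median −0.18, camera adjusted p = 0.54) TAGLN was the 1 member that passed adjusted over the list alone, and none passed over all genes. SMURF1 differed by 0.53 ± 0.17, BAMBI by −0.48 ± 0.17 and LTBP2 by 0.34 ± 0.16. The extracellular matrix and basement membrane list had a median of −0.03 and a mean of 0.02, with camera's direction down and fry's up (27 tested, camera adjusted p = 0.998). Adjusted over the list alone 2 members passed, both higher and both encoding secreted matrix proteases, MMP1 (1.11 ± 0.19) and MMP10 (1.03 ± 0.24), and none passed over all genes. LOX differed by 0.38 ± 0.17 and LAMC1 by −0.38 ± 0.17.

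Among metabolic and stress lists none was called in the main fit, and some were in other settings with the preset correlation. With an estimated correlation and with fry the adjusted p was 0.72 and 0.39 for the unfolded protein response, 0.77 and 0.39 for oxidative phosphorylation, and 0.77 and 0.65 for cholesterol synthesis. The cholesterol synthesis list had 10 of 16 tested members below 0 and a median of −0.14 (camera adjusted p = 0.16), and its shift of −0.19 was −0.35 without control replicate 1 (adjusted p = 0.00049) and −0.02 without control replicate 2 (adjusted p = 0.91). In it MSMO1, a sterol demethylation enzyme, was the 1 member that passed adjusted over the list alone (−1.06 ± 0.25), with none over all genes. The other MSMO1 probes above background differed by −1.09 and 0.08. INSIG1 differed by −0.70 ± 0.27, SQLE by −0.36 ± 0.18 and SC5D by −0.34 ± 0.21. The unfolded protein response list had 16 of 22 tested members below 0 and a median of −0.20 (camera adjusted p = 0.13); it passed in 6 of 15 other settings, with a lowest adjusted p of 0.0056. With an array left out its shift of −0.19 ran from −0.28 to −0.10. VLDLR, at −1.24 ± 0.24, was its 1 member that passed adjusted over the list alone, with none over all genes. ASNS (−0.61 ± 0.19), TRIB3 (−0.61 ± 0.28) and XBP1 (−0.37 ± 0.16) did not pass, and a second probe above background gave −0.17 for ASNS and −0.04 for XBP1. The oxidative phosphorylation list had 18 of 23 tested members above 0 and a median of 0.11 (camera adjusted p = 0.14) and passed in 4 of the 15 (lowest adjusted p = 0.011), with ATP5MC1 at 0.69 ± 0.21, NDUFA9 at 0.31 ± 0.16, COX7A2 at 0.28 ± 0.16 and ATP5PO at 0.27 ± 0.16. The hypoxia and glycolysis list had a median of 0.11 (22 tested, camera adjusted p = 0.56), with NDRG1 at −0.64 ± 0.18, BNIP3L at −0.63 ± 0.21, PFKFB4 at 0.43 ± 0.19 and PKM at 0.27 ± 0.17. Heat shock genes had a median of 0.07 (13 tested, camera adjusted p = 0.35). HSPE1 differed by 0.31 ± 0.17, DNAJA1 by −0.26 ± 0.17 and DNAJB1 by 0.24 ± 0.19, and HSPA4L, below detection in the controls, was at least 1.28-fold higher. Large ribosomal protein genes had a median of 0.02 (25 tested, camera adjusted p = 0.32), with RPL14 at 0.59 ± 0.23, RPL13 at 0.44 ± 0.16, RPL28 at 0.43 ± 0.17 and RPL30 at 0.25 ± 0.16. A second probe above background gave 0.09 for RPL14, 0.34 for RPL13, 0.17 for ATP5MC1, −0.28 for BNIP3L and 0.92 for HSPE1. The other PKM probes above background differed by 0.22 and −0.22. The medians of the uncalled unfolded protein response (percentile 0.17), TGF-beta (2.37), smooth muscle (98.06) and oxidative phosphorylation (98.76) lists also lay outside the 95% range of matched lists. In the oxidative phosphorylation, hypoxia, heat shock and ribosomal lists no member passed over all genes or adjusted over the list alone.

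**Figure D2:**
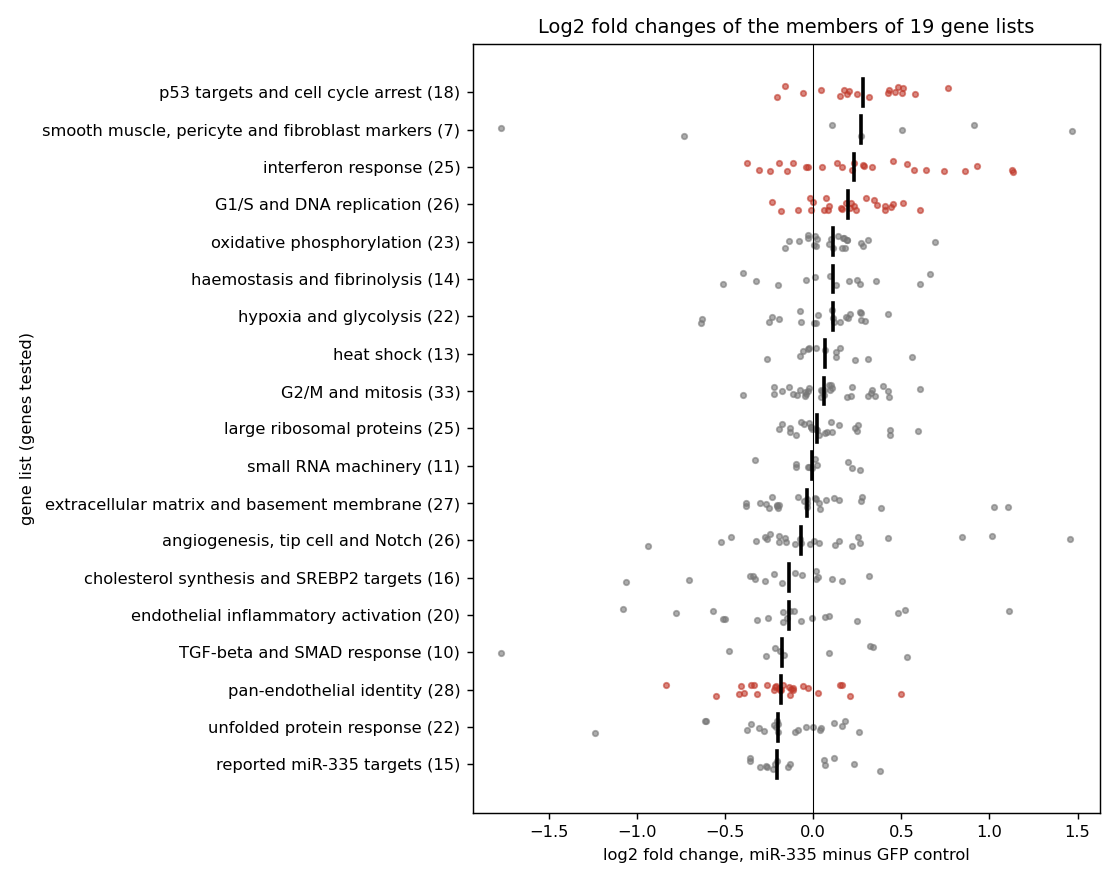
Log2 fold changes (horizontal axis, miR-335 minus GFP control) of the tested members of 19 of the 20 gene lists tested; points are genes, black bars are list medians and the number tested follows each name. The 4 lists in red had a camera adjusted p below 0.05 with the preset correlation, with medians of 0.28 (p53 targets), 0.23 (interferon response), 0.20 (G1/S) and −0.19 (pan-endothelial identity).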

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

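The settings named here were planned. Against 5 genes changed, 119 passed without background correction (61 higher, 58 lower), 99 with an offset of 50, 116 in the authors' values and 126 with an intensity trend, each including the same 5. Median scaling gave 25 (17 higher, 8 lower, against 4 and 1), also with these 5. A detection p below 0.05 gave 3, all among the 5, and no filter gave 0 of 37160 (2825 at an unadjusted p below 0.05). The fit without moderated variances gave 1, not among the 5 (1050 unadjusted). Detection on all 4 arrays gave 4, of which 2 were among the 5, and the mean of probes, the robust prior and the minimum change of 1 gave 5. With an array left out the count ran from 0 to 88, with 0 without miR-335 replicate 1 (2572 unadjusted) or replicate 2 (1389 unadjusted); a lone array is then assumed to vary like the other group. The prior degrees of freedom were 6.92, against 13.8 without background correction, 17.8 with the trend and 3.29 without the filter; the cause of these shifts was not tested. The replicate numbers do not pair the arrays: deviations of the arrays numbered 1 correlated at −0.04. A replicate block gave 363 genes at prior degrees of freedom of 46.3, a rise whose cause was not tested either. Of 20 lists, 4 were called, 1 without miR-335 replicate 1 and 7 without miR-335 replicate 2; 0 were called with an estimated correlation and 0 with fry. With an estimated correlation or fry the shifts stay the same, 0.29 for interferon (adjusted p = 0.72 and 0.37), 0.28 for p53 (0.72 and 0.23), 0.20 for G1/S (0.79 and 0.65) and −0.17 for the endothelial list (0.72 and 0.23). Fry's mixed test, which counts moves in either direction, gave 10 of the 20 lists an adjusted p below 0.05. Over the other settings, the adjusted p of the interferon list ran from 0.00019 to 0.022, of p53 from 0.00017 to 0.066, of G1/S from 1.41e-05 to 0.95 and of the endothelial list from 0.0024 to 0.15. Median scaling took the endothelial shift to −0.13. With an array left out, shifts ran from 0.24 to 0.33 for p53, from 0.021 to 0.37 for G1/S and from −0.20 to −0.15 for the endothelial list; the interferon call was kept in each. Uncalled lists near 0 changed sign: small RNA machinery under median scaling (−0.0021), without the filter (−0.012) and over left-out arrays (−0.0081 to 0.036), and over left-out arrays also extracellular matrix (−0.0026 to 0.054), G2/M (−0.094 to 0.27), hypoxia (−0.045 to 0.10), angiogenesis (−0.0018 to 0.067) and the gene AGO1 (−0.060 to 0.46). Lists not called in the main fit passed elsewhere with the preset correlation, and none did with an estimated correlation or fry: the unfolded protein response in 6 of 15 settings (lowest adjusted p = 0.0056), oxidative phosphorylation in 4 (0.011, with median scaling), G2/M in 2 (0.00051), cholesterol synthesis in 1 (0.00049; shifts over left-out arrays −0.35 to −0.02) and endothelial inflammatory activation in 1 (0.049). Detection on all 4 arrays gives 10 named genes, CCL23 and SCARNA14 among them, no value. The seed-site test and its alternatives were not run. Genes near background, such as MIR335 and MEST, limit what these arrays show.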

Other observations

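The patterns taken up in this part, and the gene groups and tests not named above, were chosen after the results were seen. The interferon and smooth muscle lists, the fits with an array left out and the other planned settings had been fixed before. A set of 108 genes, 56 higher and 52 lower and holding all 5 of the report, passed in the authors' normalized values, in the signals without background correction, which are nearly the same values, and in the fit with an intensity trend. Only 17 of the 108, the same 5 among them, also passed with median scaling. The following log2 differences and adjusted p are limma's on the authors' values. Higher were the fatty acid binding protein genes FABP4 (1.01 ± 0.13, adjusted p = 0.0048) and FABP5 (0.73 ± 0.13), and ANGPTL4, an inhibitor of lipoprotein lipase (0.65 ± 0.12). LYVE1 (0.91 ± 0.13, adjusted p = 0.0051), the secreted protease genes MMP1 (0.81 ± 0.13), MMP10 (0.84 ± 0.16) and PLAU (0.59 ± 0.13), the metallothionein gene MT1G (0.61 ± 0.13) and the p53 target PHLDA3 (0.75 ± 0.13) were higher as well, and so were MS4A6A (0.96 ± 0.13), the mast cell protease gene CPA3 (0.73 ± 0.14) and the scavenger receptor gene CD163L1 (0.63 ± 0.13). Lower were TAGLN (−1.67 ± 0.23, adjusted p = 0.0051), SLC30A3 (−1.04 ± 0.12, adjusted p = 0.0015), the glucose-responsive gene TXNIP (−1.06 ± 0.20) and the transcription factor gene FOXO1 (−0.73 ± 0.14). The alarmin gene IL33, kept in endothelial nuclei, was also lower (−0.92 ± 0.14, adjusted p = 0.0051). CD34 (−0.81 ± 0.13), VCAM1 (−0.72 ± 0.12), the water channel gene AQP1 (−0.65 ± 0.12), the sialomucin gene PODXL (−0.64 ± 0.12) and CAVIN2 (−0.82 ± 0.15) were lower too; these genes were picked by eye, and no group of them was tested.

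Small nuclear and nucleolar RNAs were higher with miR-335: 75 of 85 tested were above 0, 35 against 1 at an unadjusted p below 0.05, with a median of 0.35 (camera p = 0.067 with an estimated correlation; median 0.31 with RNAs below detection in a group set at their bound, 0.17 in the authors' values). The median lay at percentile 100 of random lists matched on level. The class was chosen after the results were seen, so this percentile alone does not decide on drift of dim probes. Some members passed the filter only through the miR-335 arrays, but among RNAs detected on all 4 arrays the median was still 0.32. Without either miR-335 array the median stayed at 0.25 or above, so 1 of these arrays does not make it alone. The upper end of the matched range, from all 4 arrays, was 0.08. A higher yield of every short RNA cannot be told apart from a change of this class: 6 of 7 other short RNAs outside it were above 0, but their median of 0.189 lay within the range of matched lists (−0.29 to 0.31), too wide for so few RNAs to decide, and 7 of 14 microRNA probes were above 0 (median 0.04). RNA length and the priming of the labelling were not tested. Members that move together on 4 arrays, which a matched list does not allow for, and an effect of miR-335 also stay open.

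ACTA2 was higher and TAGLN lower, although both mark smooth muscle. A larger share of smooth muscle, pericyte or fibroblast cells cannot be told apart from a rise of ACTA2 within endothelial cells: of the 5 other tested markers, 2 passed higher (COL3A1 and RGS5) and 1 lower (FBLN1) when adjusted over the list alone. A fault of the TAGLN probe is argued against by its other probe above background, at −1.75. ACTA2 has 1 probe here, so a fault of that probe cannot be told apart from a change of the transcript. A response of the endothelial cells to miR-335 is also open for both genes and was not tested, and the miR-335 arrays differ in TAGLN (9.21 and 10.34).

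The interferon response list lay at percentile 99.98 of lists matched on level, which argues against drift of probes of that level. With 1 array left out its shift was 0.22 or more, so no single array carries it. The call did not hold with an estimated correlation (adjusted p = 0.72 with an estimated correlation) or with fry (0.37). This loss by itself does not show members that move together. With an estimated correlation, so few arrays make a call hard to reach for any list. The estimated correlation of this list was 0.14, above the preset 0.01, so members that move together on 4 arrays stay an open explanation. A higher dose of vector in the miR-335 cells could raise these genes too, and it cannot be told apart from miR-335 itself, since 0 probes are named for GFP or the vector. A response to miR-335 and an effect of chip position, which goes with the group, also stay open, and none of these was measured.

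The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 5 genes at an adjusted p below 0.05 with limma, and 1 of the 3 splits, the real one, gave as many. The highest of the others was 0, with 228 and 331 genes at an unadjusted p below 0.05 against 1641. The other splits count a difference between the groups as spread within a pair, and they gave fewer than the 613.9 expected with no change. They therefore do not show what arrays without a group difference would give.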
